A study of Rattus norvegicus with 30 samples.

How the data were processed

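Total RNA from the left ventricle of rats was measured on 30 Affymetrix arrays, 5 biological replicates for each of 6 protocols, and handled by the standard procedures of the array's maker, per the labels. The deposited values are intensity values, 1 per probe set and array, on a linear scale. The 2% trimmed mean of each array's deposited intensity values lay between 500.8 and 501, so they had been scaled to a common mean before they were deposited; the medians ran from 114.6 to 189.2, so they had not been quantile normalized. The software that made the values, and its version, are not given in the sources used here. Of all deposited values 5 were 0 and 0 were negative. The highest correlation between 2 arrays was 0.977, and 0 pairs of arrays were identical.

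Arrays were grouped by the protocol in their labels: CTL, ISCH, IPC, APC, IPC_TRI and APC_TRI. The table held 8799 probe sets. Of these, 59 Affymetrix control probe sets were kept out of the tests and read only as quality measures, 7006 carried 1 gene symbol, 308 several, and 1426 were not named here. The 7006 stood for 4736 symbols, and 6985 of their gene identifiers were found in a rat gene reference, with 0 symbols updated.

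Values were taken as log2 of the intensity plus 16 and quantile normalized, and the 40% of probe sets with the lowest mean over all arrays were left out, which kept 5244 probe sets and 3155 genes. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with signal, and 14 contrasts and an F test of any difference among groups were drawn from it. P-values were adjusted by the Benjamini-Hochberg method for each contrast, and a probe set was called at an adjusted p under 0.05. For a gene, the 1 probe set with the highest mean over all arrays among those with 1 symbol was used, and other probe sets of the same gene were compared with it.

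Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated for each list. The 30 lists were 19 of processes and 11 of cell types, tested where 3 or more members were measured and adjusted over the lists of each contrast. List members were also adjusted over the list alone. RNA quality measures of each group were compared with CTL by 2-sided exact permutation tests, adjusted over 30 tests. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

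The groups, contrasts, fixed lists, named-gene rule and alternatives listed first below were written before the data were examined. For ISCH, IPC_TRI and APC_TRI against CTL and IPC and APC against ISCH, the rule named the 10 genes with the largest change in each direction past the threshold and up to 3 members of each fixed list, at most 30. Nppa, Nppb, Hspa1a, Fos, Hmox1, Ptgs2 and Myh6 were named there in any case. For the other contrasts it named 4 genes per direction, and where none passed, the 3 with the smallest p per direction. Up to 4 members with the smallest p were named for a list said to be changed or tested.

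These alternatives were pseudocounts of 1 and 64, no filter, 60% of probe sets left out, the values as deposited, median centring, a block for the replicate number, and a fit of only the groups of the contrast. For lists they also held the mean over each gene's probe sets and the estimated correlation, and each array was left out in turn. Alternatives chosen after seeing the data left out 2 doubted arrays together (IPC_TRI 5 and ISCH 1) or used array weights, the beta-actin 3′ to 5′ ratio as a covariate, or the bacterial spike signal as a covariate; the last 3 of these were not run for lists, apart from the fibroblast list with the spike signal. A count within 1.5 times the first was called the same. Lists of interferon-induced and cholesterol synthesis genes, and a contrast of the mean of IPC and APC with ISCH, were also chosen after seeing the data.

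The fit was tested on simulated data for the 5244 probe sets, with known changes put in. The simulated values were independent between probe sets, with 1 spread per probe set in all groups, which is what the fit assumes. The real groups were not equally alike, with a mean correlation within the group of 0.891 in IPC_TRI and 0.960 in CTL. The shares below are therefore not error rates for the real data. In ISCH minus CTL the fit recovered 26.9% of changes of 1.5-fold, 62.7% of 2-fold and 97.0% of 4-fold, with 6 false calls of 130. In IPC minus ISCH the shares were 28.4%, 62.7% and 97.0% (6 false of 131), and in APC minus ISCH 22.4%, 52.2% and 98.5% (7 of 122). In IPC minus APC they were 17.9%, 64.2% and 97.0% (6 of 125). Correlations between contrasts were set beside 100 simulations without effects and 20 splits of the shared control arrays.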

Results

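Total RNA from the left ventricle of rat hearts was measured on 30 Affymetrix arrays in 6 groups of 5. The groups were control hearts (CTL), hearts exposed to ischaemia (ISCH), hearts given ischaemic preconditioning (IPC), hearts given preconditioning with an anaesthetic (APC), and a trigger group for each kind of preconditioning (IPC_TRI and APC_TRI). Preconditioning is a mild stimulus given before a damaging ischaemia that limits the injury, and the trigger is that stimulus without the later test ischaemia. Each array held 8799 probe sets, of which 5244 probe sets and 3155 genes entered the tests. The deposited signals had been scaled to a common level, with a trimmed mean of 501 on the arrays, and the median signal ran from 115 to 189. The number of arrays, 5 per group, limits the precision of each value below. Changes are log2 fold changes ± standard error (SE) with n = 5 arrays per group, and adjusted p-values are from limma.

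**Figure D1:**
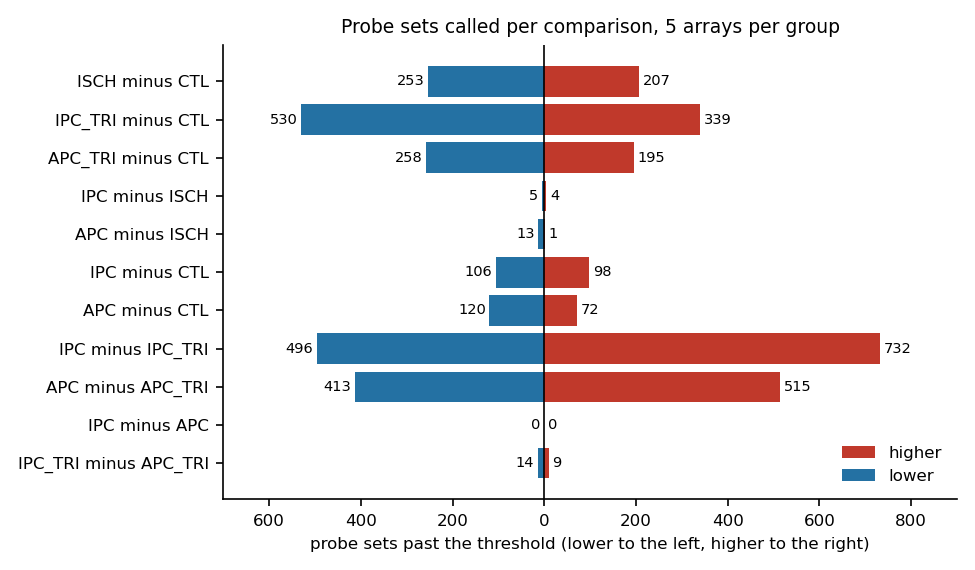
Number of probe sets past an adjusted p of 0.05 in each comparison of 2 groups, with bars to the right for higher and to the left for lower signal in the group named first. The longest bars belong to IPC minus IPC_TRI (732 higher, 496 lower), while IPC minus ISCH (4 and 5), APC minus ISCH (1 and 13) and IPC minus APC (0) are short.

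The first comparison asked what ischaemia did to hearts with no preconditioning. Jun, a transcription factor induced within minutes of stress, rose by 2.64 ± 0.22 (adjusted p = 3.9e-10), from a mean signal of 1327 ± 323 (SD, n = 5) to 8340 ± 2325. The chaperone gene Hsph1 rose by 2.55 ± 0.18 (adjusted p = 1.5e-11) and Hspa1a by 2.07 ± 0.32 (adjusted p = 2.6e-05). Mx2, a gene that interferons induce, fell by 4.98 ± 0.51 (adjusted p = 4.3e-08), from a signal of 2162 ± 799 to 51.3 ± 21.2, and the chemokine gene Cxcl10 fell by 4.87 ± 0.31 (adjusted p = 1.7e-12). In all, 460 probe sets passed, 207 higher and 253 lower, which held 107 genes that rose and 155 that fell. With array weights 933 passed, and with the bacterial spike signal as a covariate 157, both chosen after the data were seen.

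Of the other genes with the largest rises, G0s2, an inhibitor of triglyceride lipase, rose from a low mean signal, 18.9 ± 13.9 in CTL, to 268 ± 114 in ISCH (SD, n = 5). Its log2 change depended on the pseudocount, with 3.69 at 1 and 1.90 at 64, and it passed with each. The fatty acid binding protein gene Fabp4 rose by 1.97 ± 0.34 and Klf4 by 1.96 ± 0.28. Cyp4b1 (2.05 ± 0.44), Dnajb1 (1.72 ± 0.25), Rgs4 (1.68 ± 0.49) and Egfl7 (1.68 ± 0.36) completed that set. The other large falls were Rsad2 (-4.21 ± 0.30), Gbp2 (-3.50 ± 0.26), Mx1 (-2.97 ± 0.35), Cd40 (-2.91 ± 0.39), Irgm2 (-2.83 ± 0.25), Pfkfb3 (-2.61 ± 0.29), Gch1 (-2.46 ± 0.28) and Irf1 (-2.46 ± 0.31). For each of these 20 genes all 5 ISCH arrays lay outside the range of the 5 CTL arrays. Among members of the fixed lists, Nqo1 fell by 2.03 on the log2 scale, Txnip rose by 1.47 ± 0.27, Gsta1 by 0.82 ± 0.22 and the initiator caspase gene Casp2 by 1.28 ± 0.30, while Casp1 fell by 0.86. Fos rose by 1.29 ± 0.19. Nppa (-0.13 ± 0.36), Nppb (-0.41 ± 0.16) and Hmox1 (0.20 ± 0.19) did not pass.

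Some of these calls ended when 1 array was left out. Rgs4 no longer passed when any of 4 of the 10 arrays was left out (1.34 without CTL 2), Casp1 without CTL 1 (-0.77) or ISCH 2 (-0.77), and the prostaglandin synthase gene Ptgs2, at -1.33 ± 0.35, without ISCH 1 (-0.98). The heavy chain gene Myh6 had -0.42 ± 0.11 (adjusted p = 0.012), which turned to 0.08 with the values as deposited and with median centring, and it did not pass without CTL 1 (-0.34).

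**Figure D2:**
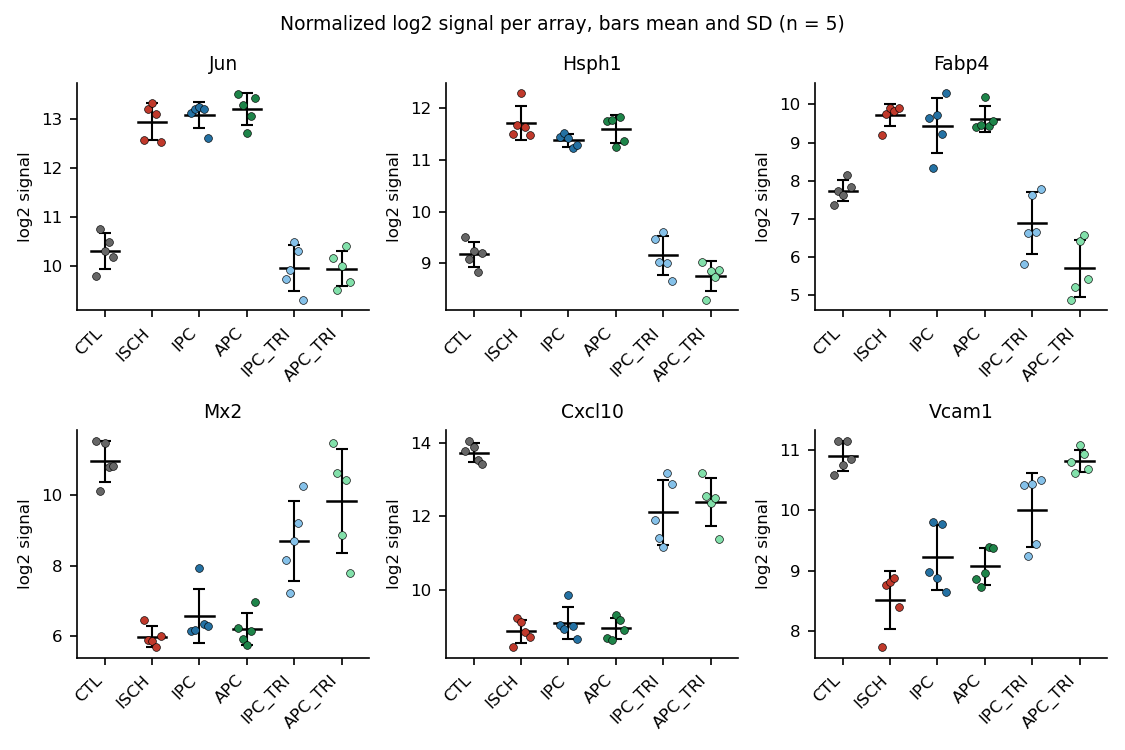
Normalized log2 signal of Jun, Hsph1, Fabp4, Mx2, Cxcl10 and Vcam1 on each array, 1 panel per gene, with 1 point per array (bars, mean and SD, n = 5) and the groups along the horizontal axis; the 6 genes were picked by hand after their values were seen. Jun and Hsph1 are high in ISCH, IPC and APC and low in CTL and both trigger groups, and Mx2 and Cxcl10 are highest in CTL.

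The list of cytokines, chemokines and adhesion molecules shifted down in ISCH. Of 39 members measured, 20 fell, 0 rose and 19 did not pass, with 22 that fell when adjusted over the list alone. The median change was -0.94 and limma's camera test gave an adjusted p of 1.9e-17, and an adjusted p of 0.0066 with an estimated correlation. Besides Cxcl10, the adhesion molecule genes Vcam1 (-2.38 ± 0.26) and Sele (-2.22) fell, as did the interleukin gene Il1a (-2.18) and the chemokine gene Ccl2 (-1.91). Markers of the endothelium, which carries such adhesion molecules, did not shift as a list (median 0.33, mean -0.06, adjusted p = 0.80). Of its 10 members Thbd rose by 0.66 while Selp (-1.94) and Sele fell.

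The list of fibroblast and extracellular matrix genes shifted up (median 0.64, adjusted p = 7.1e-08), with 7 of 14 members risen, 0 fallen, and 10 risen when adjusted over the list alone. Its call was not kept with an estimated correlation (adjusted p = 0.12). The collagen genes Col1a2 (1.44), Col1a1 (1.31) and Col3a1 (1.23) and the filament gene Vim (0.96) were among the risen. The bacterial control transcripts spiked into each sample had a mean log2 signal of 12.0 ± 0.62 in ISCH against 10.7 ± 0.70 in CTL (SD; 2-sided exact permutation p = 0.016, adjusted p = 0.060), and the brightest 1% of probe sets held 37.3 ± 4.34% of the signal against 30.5 ± 3.22% (exact p = 0.016, adjusted p = 0.060). With the spike signal as a covariate, chosen after the data were seen, the calls of Egfl7 (0.78), Txnip (1.16), Gsta1 (0.93), Casp2 (0.70), Casp1 (-0.50), Rgs4 (1.84), Hspa5 (0.66), Pdia6 (0.41), Ptgs2 (-0.88) and Myh6 (-0.27) ended.

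Of 28 immediate early genes 7 rose and 1 fell, with 8 and 3 when adjusted over the list alone (median 0.29, adjusted p = 3.7e-04; adjusted p = 0.12 with an estimated correlation). Dusp1 rose by 1.58 ± 0.17 and Nr4a1 by 1.41, while Btg1 fell by 0.68. Of 17 heat shock protein genes 5 rose and 1 fell, and 5 and 2 when adjusted over the list alone (median 0.20, adjusted p = 0.0017; adjusted p = 0.26 with an estimated correlation). Among 32 cytosolic ribosomal protein genes 4 rose and 0 fell, with 5 and 0 when adjusted over the list alone (median 0.29, adjusted p = 9.2e-05; adjusted p = 0.16 with an estimated correlation). Of 14 endoplasmic reticulum stress genes 3 rose and 0 fell, with 4 when adjusted over the list alone (median 0.32, adjusted p = 0.033; adjusted p = 0.14 with an estimated correlation): Ddit3 (0.93 ± 0.22), Hspa5 (0.58 ± 0.17) and Pdia6 (0.48 ± 0.14). This list call ended without CTL 3 (0.14), ISCH 3 (0.23) or ISCH 4 (0.27) and with both other scalings. The single calls of Hspa5 (0.52) and Pdia6 (0.43) ended with median centring, and when any of 6 and 5 of the 10 arrays was left out (0.45 without CTL 3 and 0.40 without ISCH 4).

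Of 19 genes of the citric acid cycle and pyruvate dehydrogenase 4 fell, and 12 when adjusted over the list alone (median -0.37, adjusted p = 8.2e-04; adjusted p = 0.12 with an estimated correlation), among them citrate synthase, Cs (-0.61), Got1 (-0.55), Got2 (-0.52) and Idh2 (-0.50). Of 26 genes of glycolysis and glucose use 6 fell, and 7 when adjusted over the list alone (median -0.22, adjusted p = 0.0010; adjusted p = 0.12 with an estimated correlation). Of 35 genes of fatty acid oxidation 4 fell and 1 rose, and 9 and 1 when adjusted over the list alone (median -0.31, adjusted p = 0.0060; adjusted p = 0.14 with an estimated correlation). The sarcomere list had 3 of 23 members fallen, over all genes and when adjusted over the list alone (median -0.19, adjusted p = 0.019; adjusted p = 0.26 with an estimated correlation), with a median of 0.08 on the values as deposited and with median centring, and no call without ISCH 2 (-0.18). Of 5 adipocyte markers 1, Fabp4, rose, over all genes and when adjusted over the list alone (median 0.29, adjusted p = 0.023; adjusted p = 0.14 with an estimated correlation), and the call ended without ISCH 4 (0.24).

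The other lists did not pass in ISCH minus CTL. Adjusted p was 0.087 for nerve and Schwann cell markers, 0.098 for oxidative phosphorylation, 0.13 for proteasome and ubiquitin, 0.49 for calcium-activated proteolysis and phospholipases and 0.49 for smooth muscle cells and pericytes. It was 0.51 for preconditioning signalling, 0.54 for calcium handling and ion channels, 0.57 for mast cells, 0.58 for hypoxia and angiogenesis, 0.59 for antioxidant and metal response genes and 0.73 for apoptosis. It was 0.74 for fetal and hypertrophy genes (median -0.07, mean 0.12), for red blood cells and for skeletal muscle. The remaining values were 0.80 for lymphocytes, 0.90 for glucocorticoid and circadian genes (median -0.04, mean 0.01) and 0.90 for myeloid cells (median 0.05, mean 0.00 and a test pointing down). Atrial myocardium had 0.99 (median -0.20, mean -0.06 and a test pointing up).

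**Figure D3:**
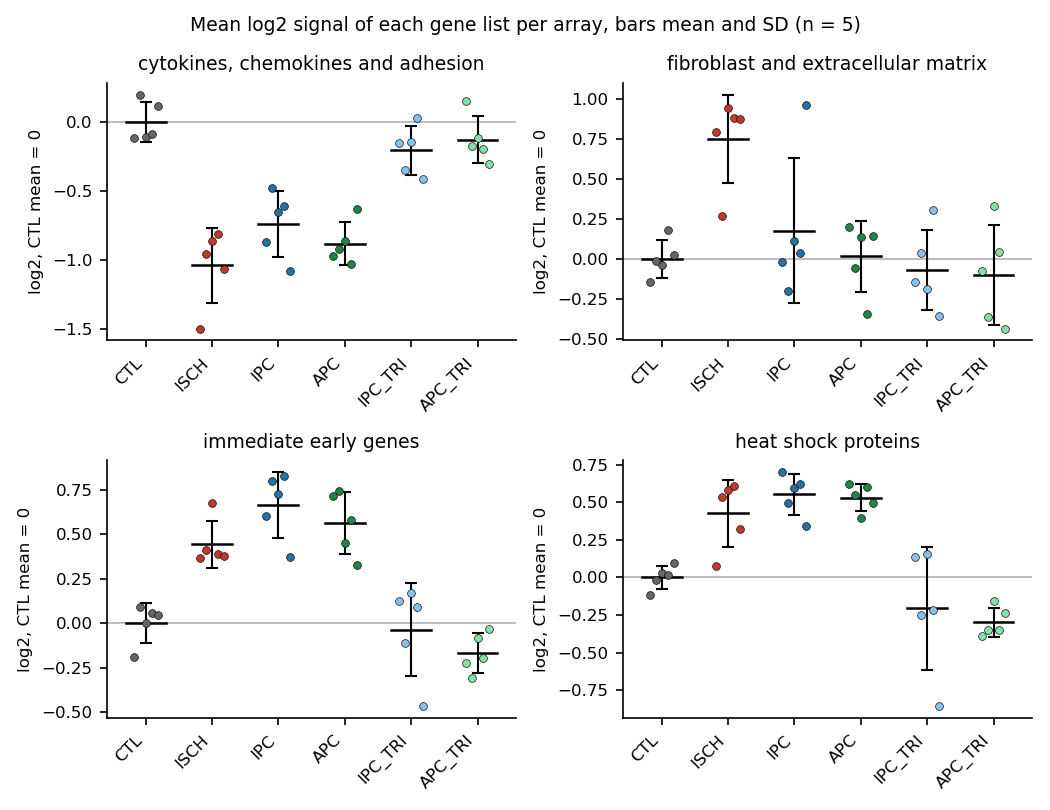
Mean log2 signal of the members of 4 gene lists on each array, with the CTL mean set to 0, 1 panel per list and 1 point per array (bars, mean and SD, n = 5). The cytokine, chemokine and adhesion list lies below 0 in ISCH, IPC and APC, and the fibroblast and extracellular matrix list is highest in ISCH.

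The central comparisons set each preconditioned group against unprotected ischaemia. In IPC minus ISCH 9 probe sets passed (4 higher, 5 lower) and in APC minus ISCH 14 (1 higher, 13 lower). Notch1, a receptor that signals between neighbouring cells, fell in both, by 0.85 ± 0.19 with IPC (adjusted p = 0.047) and by 0.99 ± 0.19 with APC (adjusted p = 0.021). In IPC minus ISCH the collagen gene Col5a1 (-0.98 ± 0.20, adjusted p = 0.034) and Pnmt, the enzyme that makes adrenaline (-1.38 ± 0.28, adjusted p = 0.034), also fell. In APC minus ISCH the giant sarcomere protein gene Ttn (-1.74 ± 0.38, adjusted p = 0.039), Rpl19l4 (-1.26 ± 0.28, adjusted p = 0.043) and the semaphorin receptor gene Nrp1 (-1.05 ± 0.20, adjusted p = 0.021) fell. All 5 arrays lay outside the range of the ISCH arrays for Pnmt in IPC and for Notch1 and Nrp1 in APC, and the groups overlapped for the others. Nppa, Nppb, Hspa1a, Fos, Hmox1, Ptgs2 and Myh6 did not pass in either comparison; their values lay between -0.28 and 0.42 with IPC and between -0.24 and 0.35 with APC.

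The fibroblast and extracellular matrix list was lower in both preconditioned groups than in ISCH. With IPC the median was -0.58 (adjusted p = 3.9e-09) and 13 of 14 members lay below 0; 0 passed over all genes and 8 fell when adjusted over the list alone. The fall was not seen in IPC 5, whose list mean against CTL was 0.96, where the other 4 IPC arrays had -0.20 to 0.11 and ISCH a mean of 0.75 ± 0.27 (SD, n = 5). With APC the median was -0.70 (adjusted p = 6.9e-14) and 14 of 14 lay below 0; 0 passed over all genes and 11 fell when adjusted over the list alone. With an estimated correlation both calls were lost (adjusted p = 0.17 and adjusted p = 0.075). The list had been higher in ISCH than in CTL, and the 5 ISCH arrays stand in the 3 comparisons.

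Genes of the citric acid cycle shifted up against ISCH, with a median of 0.27 in IPC (adjusted p = 2.6e-05; adjusted p = 0.11 with an estimated correlation) and 0.30 in APC (adjusted p = 5.7e-04; adjusted p = 0.18 with an estimated correlation). Of the 19 members 0 passed over all genes in either, and 4 rose with IPC and 0 with APC when adjusted over the list alone. Genes of glycolysis shifted up too, with medians of 0.19 and 0.19 (adjusted p = 0.0030 and 0.0083; with an estimated correlation adjusted p = 0.17 and adjusted p = 0.24). Of these 26 genes 0 passed over all genes, and 2 with IPC and 3 with APC rose when adjusted over the list alone. Ribosomal protein genes shifted down, with a median of -0.17 in IPC (adjusted p = 3.4e-05; adjusted p = 0.29 with an estimated correlation) and -0.15 in APC (adjusted p = 3.5e-04; adjusted p = 0.38 with an estimated correlation). With IPC 0 of these 32 genes passed on either count; with APC 1 fell, and 2 when adjusted over the list alone. The APC call of this list ended with median centring (-0.05).

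In IPC alone among these 2 comparisons the cytokine list (median 0.23, adjusted p = 2.0e-04; adjusted p = 0.29 with an estimated correlation) and the immediate early genes (median 0.21, adjusted p = 0.0083; adjusted p = 0.29 with an estimated correlation) passed. None of their members passed over all genes; 2 cytokine genes rose and 1 fell, and 2 immediate early genes rose, when adjusted over the list alone. The cytokine call ended without ISCH 1 (0.17), and that of the immediate early genes with the mean over each gene's probe sets (0.18). In APC the smooth muscle list passed (median -0.31, adjusted p = 0.017; adjusted p = 0.25 with an estimated correlation), with 0 of 7 members past over all genes and 2, Tagln (-1.34) and Acta2 (-1.28), lower when adjusted over the list alone; it ended without APC 1 (-0.33). The sarcomere list passed as well (median 0.16, adjusted p = 0.039; adjusted p = 0.56 with an estimated correlation), with 1 member fallen over all genes and 1 risen and 1 fallen when adjusted over the list alone. On the values as deposited and with median centring its test pointed down at medians of 0.01 and 0.07, and the call ended when any of 5 of the 10 arrays was left out (0.15 without ISCH 2). In IPC minus APC the immediate early, smooth muscle and sarcomere lists did not pass. The cytokine list passed there, but not with an estimated correlation (adjusted p = 0.65) or without IPC 2, IPC 3 or APC 4, and 0 of its 39 members passed.

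These 2 counts were the least stable. With only the groups of the contrast in the fit they were 0 and 6, and with array weights, chosen after the data were seen, 267 and 203. IPC minus ISCH called 89 probe sets without IPC 5, 3 without ISCH 4, 2 without ISCH 1 or ISCH 5, 1 without ISCH 3, IPC 1 or IPC 3, and 0 without IPC 2 or IPC 4 (limma; 568 had an unadjusted p under 0.05 with all arrays). APC minus ISCH called 33 without ISCH 2, 25 without ISCH 1, 6 without APC 1, 5 without APC 4, 4 without APC 3, and 1 without ISCH 3, ISCH 5 or APC 5 (643 had an unadjusted p under 0.05). Leaving out 1 array at a time ended the calls of Pnmt for 7 of 10 arrays, Col5a1 for 8 and Notch1 for 9 in IPC minus ISCH (-1.25 without IPC 4, -0.96 and -0.66 without IPC 2). In APC minus ISCH it ended those of Ttn for 7, Rpl19l4 for 8, Nrp1 for 4 and Notch1 for 3 (-1.62, -1.13, -0.86 and -0.94 without ISCH 3). The up and down split of APC minus ISCH was 14 and 40 with the values as deposited, and 15 and 24 with median centring. Without a filter on low values 2 and 8 probe sets passed, and the calls of Pnmt, Col5a1 and Notch1 in IPC minus ISCH and of Ttn and Rpl19l4 in APC minus ISCH ended; Notch1 in IPC minus ISCH also did not pass with median centring (-0.77). With the beta-actin 3′ to 5′ ratio as a covariate the calls of Notch1 in IPC minus ISCH (-0.85) and of Ttn (-1.43), Rpl19l4 (-1.16) and Nrp1 (-1.05) in APC minus ISCH ended. With the spike signal as a covariate 0 probe sets passed in either comparison. Both covariates were chosen after the data were seen. Over the alternatives run for genes, the spike signal included, IPC minus ISCH had -1.61 to -1.12 for Pnmt, -1.17 to -0.89 for Col5a1 and -1.06 to -0.66 for Notch1. In APC minus ISCH the ranges were -2.05 to -1.275 for Ttn, -1.59 to -1.10 for Rpl19l4, -1.21 to -0.86 for Nrp1 and -1.06 to -0.89 for Notch1.

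The preconditioned hearts were also set against CTL. In IPC minus CTL 204 probe sets passed, 98 higher and 106 lower (48 genes up, 66 down). In APC minus CTL 192 passed, 72 higher and 120 lower (34 genes up, 69 down). With array weights, chosen after the data were seen, the counts were 398 and 383, and with only the groups of the contrast in the fit 278 and 298. In IPC, Jun rose by 2.77 ± 0.22, Klf4 by 2.49 ± 0.28 and Hsph1 by 2.21 ± 0.18. Cxcl10 (-4.64 ± 0.31), Mx2 (-4.39 ± 0.51), Rsad2 (-3.96 ± 0.30) and Gbp2 (-3.02 ± 0.26) fell. In APC the corresponding values were 2.90 ± 0.22 for Jun, 2.43 ± 0.18 for Hsph1, 2.18 ± 0.28 for Klf4, -4.79 ± 0.31 for Cxcl10, -4.77 ± 0.51 for Mx2, -4.05 ± 0.30 for Rsad2 and -3.40 ± 0.26 for Gbp2. G0s2 rose too, from its low mean signal in CTL to 286 ± 85.3 in IPC and 190 ± 89.7 in APC (SD, n = 5), with log2 changes between 3.92 and 2.07 in IPC and between 3.28 and 1.59 in APC for pseudocounts of 1 and 64. The largest adjusted p among these 8 genes was 0.0010, and all 5 arrays of each group lay outside the CTL range.

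The cytokine list shifted down in IPC (median -0.69, adjusted p = 1.3e-14; 1 of 39 rose and 15 fell, with 2 and 19 when adjusted over the list alone). It also shifted down in APC (median -0.89, adjusted p = 2.3e-20; 0 rose and 16 fell, with 2 and 23 when adjusted over the list alone), where Ccl2 fell by 1.88 and Cx3cl1 by 2.50. Immediate early genes shifted up in both (median 0.48, adjusted p = 1.1e-12, 9 of 28 risen and 0 fallen in IPC; median 0.44, adjusted p = 3.1e-08, 6 risen and 1 fallen in APC). Adjusted over the list alone, 12 rose and 1 fell in IPC, and 10 rose and 1 fell in APC. With an estimated correlation these 4 calls held (adjusted p = 0.0085, 0.0027, 0.0035 and 0.018 in the order given). Heat shock genes rose as a list in IPC (median 0.29, adjusted p = 5.0e-07; adjusted p = 0.12 with an estimated correlation) and in APC (median 0.27, adjusted p = 2.0e-06; adjusted p = 0.15 with an estimated correlation). Of the 17, 6 rose in IPC and 4 in APC, with 6 and 6 when adjusted over the list alone, among them Dnajb1 (1.82 in IPC) and Dnaja1 (1.52 in IPC and 1.32 in APC). The endoplasmic reticulum stress list rose in IPC (median 0.17, adjusted p = 0.0072; adjusted p = 0.098 with an estimated correlation) and in APC (median 0.31, adjusted p = 0.0018; adjusted p = 0.046 with an estimated correlation). In each, 3 of its 14 members rose and 0 fell, with 3 in IPC and 4 in APC when adjusted over the list alone; Ddit3 rose by 1.15 and 1.28.

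The trigger comparisons asked what the preconditioning stimulus did without the test ischaemia. IPC_TRI minus CTL called 869 probe sets, 339 higher and 530 lower (219 genes up, 276 down), and APC_TRI minus CTL 453, 195 higher and 258 lower (114 genes up, 135 down). Which trigger called more depended on the fit: with only the groups of the contrast the counts were 238 and 821, with array weights 394 and 1065, and without IPC_TRI 5 and ISCH 1 together 736 and 816, the last 2 chosen after the data were seen. The IPC_TRI arrays were less alike (mean correlation within the group 0.8908) than those of APC_TRI (0.9445) or CTL (0.9597). The fit of all 6 groups uses 1 spread per probe set for all of them, so its SEs do not carry that difference. The stress genes of the ischaemic groups were not among the largest changes: Hspa1a (-0.10 ± 0.32) and Fos (0.32 ± 0.19) did not pass in IPC_TRI, and in APC_TRI Hspa1a fell by 1.25 while Fos (0.02 ± 0.19) did not pass. Rfk, which makes flavin cofactors from riboflavin, rose by 1.66 ± 0.27 in IPC_TRI (adjusted p = 1.6e-04) and 1.36 ± 0.27 in APC_TRI (adjusted p = 0.0019). The G protein gene Gnai2 rose by 1.45 ± 0.20 and 1.27 ± 0.20, and the ubiquitin-conjugating enzyme gene Cdc34 by 1.44 ± 0.17 and 1.11 ± 0.17. The mitochondrial carrier gene Slc25a14 fell by 1.80 ± 0.35 and 1.84 ± 0.35, and the kinase gene Lyn by 1.83 ± 0.41 and 1.60 ± 0.41.

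In IPC_TRI, Kctd13 (3.05 ± 0.92), Pnck (2.25 ± 0.66), Serpina3l (1.85 ± 0.47), Syt5 (1.69 ± 0.40), Cdo1 (1.60 ± 0.38), Ces1dl1 (1.51 ± 0.29) and Cyp2j3 (1.44 ± 0.35) also rose. Mx2 (-2.25 ± 0.51), Rasl11b (-2.21 ± 0.30), Sptan1 (-2.00 ± 0.31), Pnmt (-2.00 ± 0.28), Tnks2 (-1.95 ± 0.32), Acadsb (-1.93 ± 0.53), Crk (-1.82 ± 0.39) and B4galt1 (-1.78 ± 0.50) fell. Among list members Ier5 (1.22 ± 0.31), Calr (0.67 ± 0.20) and Hmox1 (0.60 ± 0.19) were higher, and Hspa9 (-1.50 ± 0.38), Gclc (-1.37 ± 0.40), Klf4 (-1.02 ± 0.28), Hyou1, Ddit3 (-0.99 ± 0.22), Atf3 (-0.89 ± 0.18), Cryab (-0.55 ± 0.18) and Hspb6 (-0.43 ± 0.15) lower. Myh6 had -0.40 ± 0.11, which turned to 0.09 with the values as deposited and 0.05 with median centring. Nppa (0.31 ± 0.36), Nppb (0.10 ± 0.16) and Ptgs2 (-0.44 ± 0.35) did not pass.

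A single array decided some of these calls. Without IPC_TRI 5 those of Acadsb (-1.43), B4galt1 (-1.42), Hyou1 (-0.72), Calr (0.55), Cryab (-0.27) and Hspb6 (-0.28) ended, and the fall of Klf4 shrank from -1.02 to -0.58, which still passed. Those of Acadsb (-1.49), Gclc (-1.03) and Kctd13 (2.03) ended without IPC_TRI 2, and those of Kctd13 (2.66 and 2.74) and Calr (0.62 and 0.61) also without CTL 2 or CTL 4. Myh6 did not pass without CTL 1 (-0.31), and Cryab, Hspb6 and Hmox1 lost their calls for 5, 6 and 4 of the 10 arrays. Scaling also ended calls: the values as deposited and median centring gave -0.20 and -0.25 for Cryab, -0.18 and -0.23 for Hspb6, and 0.51 and 0.46 for Hmox1, and median centring 0.55 for Calr. Hspb6 did not pass without a filter on low values. With array weights Kctd13 (2.38), Pnck (1.81), Acadsb (-1.20), B4galt1 (-1.09), Gclc (-1.17), Klf4 (-0.72), Hyou1 (-0.69), Cryab (-0.37), Hspb6 (-0.36), Myh6 (-0.37) and Hmox1 (0.59) did not pass. The whole count was 567 without CTL 4.

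In APC_TRI, the cell cycle inhibitor gene Cdkn1a (1.59 ± 0.40), the water channel gene Aqp2 (1.54 ± 0.36), Hist4h4 (1.28 ± 0.28), Apom, Espn (1.17 ± 0.33), Tmtc3 (1.09 ± 0.35) and Timm44 (1.09 ± 0.27) also rose. Fabp4 (-2.04 ± 0.34), Slc6a17 (-1.77 ± 0.49), the squalene synthase gene Fdft1 (-1.69 ± 0.47), Dlgap4 (-1.55 ± 0.39), Wt1 (-1.54 ± 0.43), Gbp2 (-1.46 ± 0.26), Ddost (-1.45 ± 0.35) and Tmem183a (-1.43 ± 0.39) fell. Among list members Nr4a1 (0.74 ± 0.19) and A2m (0.82 ± 0.20) rose, and Cxcl10 (-1.34 ± 0.31), Plat (-1.13 ± 0.18), Dnaja1 (-1.05 ± 0.23), Prdx1 (-0.83 ± 0.16), Pdia3 (-0.76 ± 0.17), Sgk1 (-0.76 ± 0.20) and Prdx6 (-0.51 ± 0.16) fell. Nppa (0.73 ± 0.36), Nppb (-0.00 ± 0.16), Hmox1 (0.51 ± 0.19), Ptgs2 (-0.36 ± 0.35) and Myh6 (-0.26 ± 0.11) did not pass. The calls of Wt1 ended without APC_TRI 3 (-1.29) or APC_TRI 4 (-1.25), of Slc6a17 without CTL 2 (-1.57), APC_TRI 4 (-1.62) or APC_TRI 5 (-1.55), and of Sgk1 without CTL 2 (-0.69). Without a filter on low values those of Apom, Tmtc3 and Prdx6 ended, and that of Prdx6 also with median centring (-0.55) and those of Apom (1.31) and Tmtc3 (1.33) with a pseudocount of 1. Apom, Tmtc3, Prdx6, Espn and Fdft1 lost theirs for 9, 8, 6, 4 and 4 of the 10 arrays (0.88 without CTL 2, 0.88 without CTL 3, -0.40 without CTL 4, 0.90 without CTL 2 and -1.51 without APC_TRI 5), and the whole count was 282 without CTL 4.

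None of the 30 fixed lists passed in either trigger comparison. The smallest adjusted p in IPC_TRI was 0.064 for fatty acid oxidation (median -0.31), where 7 of 35 members fell and 3 rose, with 14 and 4 when adjusted over the list alone. Acadm fell by 1.36, Cpt1a by 1.21 and Cd36 by 1.18, and the uncoupling protein gene Ucp2 rose by 0.90. In APC_TRI the smallest was 0.13, shared by heat shock proteins, fatty acid oxidation, the citric acid cycle and oxidative phosphorylation. Pdhb, a subunit of pyruvate dehydrogenase, fell in both (-1.34 and -0.98), as did Uqcrc2, a subunit of respiratory complex III (-1.17 and -1.30).

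RNA control probe sets moved with the trigger groups. The ratio of the middle to the 3′ beta-actin control was 2.33 ± 0.35 in IPC_TRI and 2.33 ± 0.28 in APC_TRI against 1.29 ± 0.30 in CTL (SD, n = 5; 2-sided exact permutation p = 0.0079, adjusted p = 0.048 over 30 tests, for each). All 5 arrays of each trigger group lay above the CTL arrays. The 3′ to 5′ ratio of the GAPDH control was 1.10 ± 0.08 and 1.15 ± 0.12 against 0.960 ± 0.067 (exact p = 0.0079, adjusted p = 0.048, for each). The beta-actin 3′ to 5′ ratio was 0.748 ± 0.193 in IPC_TRI (exact p = 0.016, adjusted p = 0.060) and 0.792 ± 0.154 in APC_TRI (exact p = 0.040, adjusted p = 0.11) against 1.07 ± 0.17. With that ratio as a covariate, chosen after the data were seen, 430 probe sets passed in IPC_TRI minus CTL and 274 in APC_TRI minus CTL. Over the probe sets called without it, the median size went from 0.87 to 0.79 and the median SE from 0.23 to 0.27 in IPC_TRI, and from 0.84 to 0.79 and from 0.21 to 0.23 in APC_TRI. The IPC_TRI calls of Pnck (2.43), Syt5 (1.06), Cyp2j3 (1.12), Acadsb (-1.69), B4galt1 (-1.60), Ier5 (1.08), Klf4 (-0.59), Hspa9 (-1.25), Cryab (-0.33), Hspb6 (-0.30), Hyou1 (-0.93), Ddit3 (-0.60), Calr (0.46) and Hmox1 (0.68) ended. So did the APC_TRI calls of Cdkn1a (1.14), Apom (1.26), Espn (1.24), Tmtc3 (1.13), Timm44 (0.94), Slc6a17 (-1.72), Lyn (-1.43), Dlgap4 (-1.38), Tmem183a (-1.31), Hspa1a (-1.13), Prdx6 (-0.38) and A2m (0.69).

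**Figure D4:**
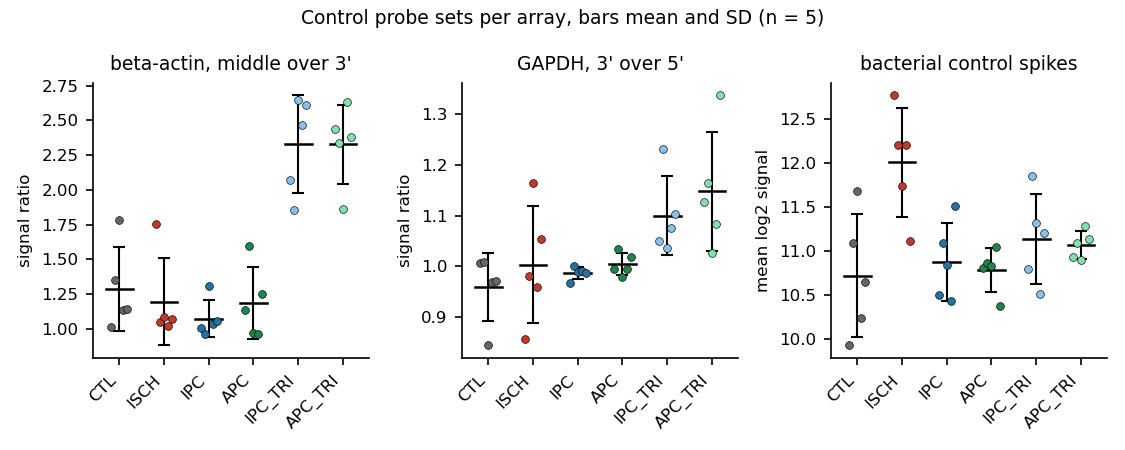
Signal ratio of the middle to the 3′ beta-actin control, signal ratio of the 3′ to the 5′ GAPDH control, and mean log2 signal of the bacterial spikes, with 1 point per array and the groups along the horizontal axis (bars, mean and SD, n = 5). All IPC_TRI and APC_TRI arrays lie above the CTL arrays in the beta-actin ratio, with means of 2.33 and 2.33 against 1.29.

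Other probe sets of the called genes followed less often in the trigger groups than in the ischaemic ones by their point values; this difference was not tested. Among called genes with a second probe set of another source sequence, the second had the same sign in 67 of 76 genes in ISCH minus CTL (88.2%, Wilson 95% interval 79.0 to 93.6). It had the same sign in 72 of 105 in IPC_TRI minus CTL (68.6%, 59.2 to 76.7) and in 38 of 58 in APC_TRI minus CTL (65.5%, 52.7 to 76.4). The median ratio of the second change to the first was 0.83, 0.16 and 0.27. For Cdo1 the second probe set had -0.20, for Hyou1 0.14, for Hmox1 -0.27 and for Lyn -0.10 in IPC_TRI, and for Pdia3 0.74 in APC_TRI. Calr had -0.73, past the threshold in the other direction, and -0.02 on its other 2 probe sets in IPC_TRI. Gnai2 had 0.14 to 0.33 and 0.07 to 0.34 on its others in the 2 trigger groups.

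**Figure D5:**
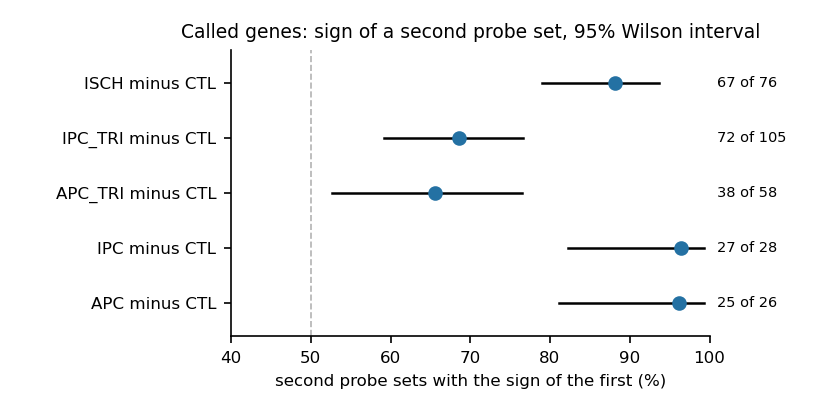
Percentage of called genes whose second probe set has the same sign as the first, 1 point per comparison with CTL and its Wilson 95% interval. The points are 88.2% in ISCH, 68.6% in IPC_TRI and 65.5% in APC_TRI, against 96.4% in IPC and 96.2% in APC.

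Setting each full protocol against its own trigger was meant to measure the test ischaemia in a preconditioned heart. Such a comparison also carries the shift of the trigger groups in the RNA control ratios. The middle to 3′ beta-actin ratio was 2.33 in both trigger groups, 1.07 in IPC and 1.18 in APC. IPC minus IPC_TRI called 1228 probe sets, 732 higher and 496 lower (386 genes up, 335 down), and APC minus APC_TRI 928, 515 higher and 413 lower (281 genes up, 263 down). This order was also reversed with only the groups of the contrast in the fit (526 and 1246), with array weights (794 and 1518) and without IPC_TRI 5 and ISCH 1 (1036 and 1251). With the values as deposited the numbers higher and lower were 598 and 574 with IPC and 495 and 501 with APC. In the first, Klf4 rose by 3.51 ± 0.28, Jun by 3.12 ± 0.22, the small GTPase gene Rasl11b by 3.08 ± 0.30 and Fabp4 by 2.54 ± 0.34, and Cxcl10 (-3.01 ± 0.31), Rsad2 (-2.60 ± 0.30), Cx3cl1 (-2.38 ± 0.32) and Mx2 (-2.14 ± 0.51) fell. In the second, Fabp4 rose by 3.91 ± 0.34, Jun by 3.25 ± 0.22, Hspa1a by 3.08 ± 0.32 and Hsph1 by 2.85 ± 0.18, and Mx2 (-3.64 ± 0.51), Cxcl10 (-3.45 ± 0.31), Cx3cl1 (-3.43 ± 0.32) and Rsad2 (-2.87 ± 0.30) fell. The fall of Mx2 in IPC minus IPC_TRI was -0.21 with the beta-actin 3′ to 5′ ratio as a covariate, where it did not pass. With that covariate 255 probe sets and 614 passed in the 2 comparisons. Second probe sets had the same sign in 103 of 161 genes and in 94 of 125.

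The same 4 lists passed in both. Of 28 immediate early genes 14 rose and 1 fell in IPC minus IPC_TRI (median 0.70, adjusted p = 1.3e-05; adjusted p = 0.15 with an estimated correlation) and 11 rose and 1 fell in APC minus APC_TRI (median 0.50, adjusted p = 2.7e-06; adjusted p = 0.12 with an estimated correlation). Of 17 heat shock genes 8 rose and 0 fell in each (median 0.63, adjusted p = 2.1e-05, and adjusted p = 0.29 with an estimated correlation; median 0.53, adjusted p = 3.8e-06, and adjusted p = 0.17 with an estimated correlation). Of 39 cytokine genes 3 rose and 17 fell in each (median -0.52, adjusted p = 6.7e-05, and adjusted p = 0.29 with an estimated correlation; median -0.67, adjusted p = 9.8e-08, and adjusted p = 0.12 with an estimated correlation). Nfkbia, the inhibitor of NF-kB, fell by 1.52 and 1.88, and Plat, a plasminogen activator, rose by 1.65 and 1.46. Of 14 endoplasmic reticulum stress genes 8 rose and 1 fell with IPC (median 0.56, adjusted p = 0.011; adjusted p = 0.18 with an estimated correlation) and 6 rose and 0 fell with APC (median 0.51, adjusted p = 0.021; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, the counts risen and fallen with IPC were 15 and 1, 10 and 0, 3 and 18, and 8 and 1 in that order, and with APC 12 and 1, 8 and 0, 3 and 18, and 6 and 0.

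IPC and APC hearts were set against each other to compare the 2 kinds of preconditioning. No probe set passed in limma, 0 of 5244, with 137 at an unadjusted p under 0.05. The genes with the smallest p were Anxa1 (0.66 ± 0.19), Ttn (1.28 ± 0.38) and Cx3cl1 (0.97 ± 0.32) on the IPC side, and Pnmt (-1.47 ± 0.28, adjusted p = 0.070), Ppp1r10 (-0.72 ± 0.22) and Glp1r (-0.63 ± 0.21) on the APC side. Pnmt passed with the values as deposited (-1.53), with median centring (-1.53), with 60% of probe sets left out (-1.47), with array weights (-1.62) and without APC 3 (-1.62), the 1 array whose removal gave a count of 1. The cytokine list stood higher in IPC (median 0.15, adjusted p = 0.0097; adjusted p = 0.65 with an estimated correlation), with 0 of 39 members past over all genes and 0 adjusted over the list alone. That call ended without IPC 2 (0.09), IPC 3 (0.13) or APC 4 (0.20).

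Between the 2 triggers 23 probe sets passed, 9 higher in IPC_TRI and 14 lower (4 genes up, 7 down), and none of the 30 fixed lists passed, with a smallest adjusted p of 0.75. With only these 2 groups in the fit 0 probe sets passed, so none of the calls named here held in that fit. The growth factor gene Areg (1.44 ± 0.32), Nme6 (1.28 ± 0.23), Uck2 (1.26 ± 0.25) and Fdx1 (0.83 ± 0.16) were higher in IPC_TRI. The desaturase gene Scd2 (-1.89 ± 0.28), Lct (-1.85 ± 0.41), Pnmt (-1.34 ± 0.28) and Zc3hc1 (-1.31 ± 0.26) were higher in APC_TRI. Lct did not pass with the values as deposited (-1.63) or median centring (-1.67), nor Pnmt with the values as deposited (-1.17), nor Areg with a pseudocount of 64 (0.93). With array weights Areg (1.36), Nme6 (1.13), Fdx1 (0.78), Lct (-1.67), Pnmt (-1.21) and Zc3hc1 (-1.20) did not pass. Second probe sets had -0.02 for Fdx1, -0.29 and 0.12 for Scd2 and -0.00 for Lct. The count was 91 without IPC_TRI 3, 79 without IPC_TRI 5, 49 without IPC_TRI 4, 37 without IPC_TRI 1, 35 without IPC_TRI 2 and 8 without APC_TRI 4. Lct lost its call without APC_TRI 3 (-1.78) or APC_TRI 4 (-1.78), Pnmt without IPC_TRI 2 (-1.16), APC_TRI 3 (-1.27) or APC_TRI 4 (-1.36), and Areg for 4 of 10 arrays (1.26 without APC_TRI 4).

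Whether the step from trigger to full protocol differed from the step from CTL to ISCH was tested as an interaction. It passed for 714 probe sets with IPC (443 higher, 271 lower; 409 genes) and 431 with APC (252 higher, 179 lower; 247 genes). The trigger groups that it subtracts differed from CTL in the RNA control ratios, and with the beta-actin 3′ to 5′ ratio as a covariate 440 and 433 passed. With only the groups of the contrast in the fit the counts were 452 and 786, and with array weights 614 and 990, so that their order was reversed. Second probe sets had the same sign in 71 of 96 genes with IPC and 44 of 60 with APC. Fdft1 had the largest positive value, 2.99 ± 0.66 with IPC and 3.63 ± 0.66 with APC, and the lipid synthesis gene Gpam had 2.98 ± 0.79 and 2.93 ± 0.79. With IPC, Mx2 (2.85 ± 0.72) and B4galt1 (2.69 ± 0.71) were positive and Kctd13 (-4.22 ± 1.30), Syt5 (-2.84 ± 0.56), the cytokine gene Lif (-2.42 ± 0.56) and Serpina3l (-2.38 ± 0.66) negative. With APC, Slc25a14 (3.15 ± 0.49) and Smad7 (3.03 ± 0.65) were positive and Kctd13 (-4.21 ± 1.30), Cyp2c13 (-2.17 ± 0.62), Tagln (-1.94 ± 0.49) and Acta2 (-1.91 ± 0.48) negative. Kctd13 lost its call for 6 and 11 of 20 arrays (-3.81 without IPC 4, -3.82 without CTL 2) and Cyp2c13 for 6 (-1.92 without CTL 2). Kctd13 with APC also did not pass without a filter on low values, nor Kctd13 with IPC with array weights (-3.65), nor Gpam (2.20) and B4galt1 (1.86) with IPC without IPC_TRI 5 and ISCH 1. With the spike signal as a covariate 70 and 36 probe sets passed, and of these genes Syt5 and Serpina3l with IPC and Slc25a14 with APC kept their calls.

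The citric acid cycle list was positive in both interactions, with 7 of 19 members past with IPC (median 0.54, adjusted p = 6.2e-04; adjusted p = 0.25 with an estimated correlation) and 5 with APC (median 0.35, adjusted p = 0.0033; adjusted p = 0.58 with an estimated correlation), and 10 and 7 when adjusted over the list alone. Pdhb had 1.82 ± 0.20 and 1.30 ± 0.20. Fatty acid oxidation was positive with IPC (7 members up, 1 down; median 0.46, adjusted p = 0.010; adjusted p = 0.42 with an estimated correlation) and APC (6 up, 1 down; median 0.46, adjusted p = 0.021; adjusted p = 0.58 with an estimated correlation), with 11 and 3, and 8 and 1, when adjusted over the list alone; Acadm had 1.79 and 1.25. The fibroblast list was negative with IPC (0 up, 2 down; median -0.48, adjusted p = 0.028; adjusted p = 0.55 with an estimated correlation) and APC (0 up, 3 down; median -0.55, adjusted p = 0.0033; adjusted p = 0.58 with an estimated correlation), with 4 and 3 down when adjusted over the list alone. The cytokine list was positive with IPC (7 up, 2 down; median 0.67, adjusted p = 0.033; adjusted p = 0.55 with an estimated correlation), with 12 and 3 when adjusted over the list alone. The fatty acid call with APC ended without ISCH 3 (0.44). The fibroblast call with IPC ended without ISCH 3 (-0.40), ISCH 4 (-0.39), IPC 2 (-0.37) or IPC_TRI 4 (-0.35). The cytokine call ended without CTL 2 (0.65), CTL 5 (0.69), ISCH 1 (0.51), IPC 2 (0.59), IPC 4 (0.67), IPC_TRI 2 (0.61) or IPC_TRI 3 (0.71).

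The mean of the 3 groups with test ischaemia against the mean of the 3 without it called 1498 probe sets, 840 higher and 658 lower (445 genes up, 428 down). With the values as deposited 742 were higher and 753 lower. With the beta-actin 3′ to 5′ ratio as a covariate, a measure that was lower in the trigger groups on the side without test ischaemia, 487 passed. Jun rose by 3.01 ± 0.13, Fabp4 by 2.81 ± 0.20, Klf4 by 2.73 ± 0.16 and Hsph1 by 2.54 ± 0.10. Cxcl10 (-3.78 ± 0.18), Mx2 (-3.59 ± 0.30), Rsad2 (-3.23 ± 0.17) and Cx3cl1 (-2.65 ± 0.19) fell. Of 39 cytokine genes 3 rose and 23 fell (median -0.67, adjusted p = 2.6e-11) and of 28 immediate early genes 14 rose and 1 fell (median 0.31, adjusted p = 1.9e-07); both calls held with an estimated correlation (adjusted p = 0.029 for each). Of 17 heat shock genes 8 rose (median 0.33, adjusted p = 1.4e-06; adjusted p = 0.14 with an estimated correlation), of 14 endoplasmic reticulum stress genes 8 rose (median 0.45, adjusted p = 0.0032; adjusted p = 0.063 with an estimated correlation), and of 14 fibroblast genes 8 rose and 1 fell (median 0.51, adjusted p = 0.014; adjusted p = 0.82 with an estimated correlation). Adjusted over the list alone, these counts were 3 and 24, 15 and 1, 8 and 0, 8 and 1, and 8 and 1. The fibroblast call ended without IPC 5 (0.43). Some difference among the 6 groups was found for 1658 probe sets (963 genes), and for 749 with that covariate.

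Comparisons that share a control group resemble each other for that reason alone, so each correlation across the 5244 probe sets, which are not independent, is given beside a simulation without effects. IPC_TRI and APC_TRI minus CTL correlated at r = 0.71, against 0.50 simulated and a median of 0.56 when the CTL arrays were split. The covariance was 0.191 against 0.0442 simulated and 0.167 split, and 286 probe sets were called in the same direction in both, 0 in opposite directions, where independent lists, which these are not, would share 12.6 higher and 26.1 lower. With the CTL arrays split, which leaves fewer arrays in each comparison, a median of 54 calls were shared (32 to 74 over 20 splits). IPC minus CTL and ISCH minus CTL had r = 0.76 (0.50 simulated, 0.59 split; covariance 0.179 against 0.0438 and 0.152), with 157 shared calls, 86.5 with CTL split (74 to 92), against 3.87 higher and 5.11 lower expected of independent lists. APC minus CTL and ISCH minus CTL had r = 0.75 (0.50 simulated, 0.58 split; covariance 0.182 against 0.0440 and 0.156), with 156 shared calls, 93.5 with CTL split (84 to 99), against 2.84 higher and 5.79 lower. IPC and APC minus ISCH had r = 0.77 (0.50 simulated, 0.30 split; covariance 0.0959 against 0.0436 and 0.0513), with 2 shared calls, both lower, 0 with ISCH split (0 in each of 20 splits), against 0.0124 lower. With no shared arrays, ISCH minus CTL correlated at 0.18 with IPC minus IPC_TRI (163 shared calls in the same direction, 35 opposite) and at 0.30 with APC minus APC_TRI (178 and 21), with simulated values of -0.00 and 0.00. IPC_TRI minus CTL had r = -0.31 with IPC minus ISCH (-0.0021 simulated), and APC_TRI minus CTL had r = -0.28 with APC minus ISCH (0.00069 simulated).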

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

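The rules for single samples and for differences between groups were set before the data were examined. The 3 patterns weighed below and the tests of their explanations were chosen only after the patterns were seen; the limits of each test were written before it was run, except for the endothelial and myeloid markers of the cytokine list, whose limit was written afterwards. A sample was marked when its gap to the nearest of the other 4 took more than 0.71 of the group's range, which chance flags about 1 in 20 groups. Of 303 groups tested 31 were marked: 17 of 220 for genes, 5 of 35 for lists and 9 of 48 for quality measures. ISCH 1 was marked 7 times, IPC 5 5 times and IPC_TRI 5 4 times.

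Among log2 signals of genes, IPC_TRI 5 was lowest of its group for Klf4 (6.82, the others 8.75 to 9.35), Cryab (13.24, others 14.54 to 14.86), Hspb6 (13.45, others 14.13 to 14.29) and Hspa1a (10.58, others 12.31 to 12.83). ISCH 1 was lowest for Cyp4b1 (7.71, others 8.38 to 8.46), Fabp4 (9.21, others 9.75 to 9.91) and Irf1 (8.45, others 10.17 to 10.33). ISCH 3 was highest for Hsph1 (12.29, others 11.48 to 11.67) and Notch1 (10.46, others 10.18 to 10.21). CTL 3 was highest for G0s2 (5.88, others 4.75 to 5.03), and CTL 4 for Klf4 (10.09, others 9.43 to 9.59) and Prdx6 (11.57, others 11.01 to 11.09). APC_TRI 5 was highest for Rfk (8.32, others 7.42 to 7.66), APC_TRI 3 highest for Nppa (13.09, others 10.44 to 11.12) and APC_TRI 4 lowest for Ddost (4.54, others 5.94 to 6.51). IPC 5 was highest for Col5a1 (10.54, others 9.44 to 9.72) and lowest for Fos (13.53, others 14.09 to 14.28).

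Among list means, as log2 against the CTL mean, IPC 5 stood apart for the fibroblast list (0.96, others -0.20 to 0.11), ribosomal proteins (0.34, others -0.06 to 0.05) and glycolysis (-0.33, others -0.12 to -0.04). ISCH 2 was lowest for the fibroblast list (0.27, others 0.79 to 0.94) and ISCH 3 highest for immediate early genes (0.68, others 0.37 to 0.41). Among quality measures, ISCH 1 had a mean correlation of 0.891 with all other arrays (others of its group 0.922 to 0.929) and 0.907 within its group (others 0.942 to 0.947). Its brightest 1% of probe sets held 44.9% of the signal (others 33.7 to 36.4), and its middle to 3′ beta-actin ratio was 1.75 (others 1.02 to 1.09). That ratio was 1.31 in IPC 3 (others 0.964 to 1.05), whose 3′ to 5′ beta-actin ratio was 0.921 (others 1.34 to 1.40). The brightest 1% held 41.6% in IPC_TRI 2 (others 35.6 to 37.1), the GAPDH ratio of CTL 3 was 0.845 (others 0.970 to 1.01), and the median signal of APC 1 was 148.2 (others 114.6 to 124).

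A difference between the step from trigger to full protocol and the step from CTL to ISCH passed in 20 of 72 tests of named genes. Over all 5244 probe sets 714 passed with IPC and 431 with APC. The tested genes were those named for ISCH minus CTL, largely for their changes there, and that step is subtracted in the difference. Such a choice pushes the difference away from the sign of the ISCH change, so the 20 are not a result about these genes. With IPC the differences were 2.85 for Mx2, 2.10 for Gch1, 1.96 for Gbp2, 1.86 for Cxcl10, 1.74 for Irgm2, 1.61 for Rsad2, 1.59 for Vcam1, 1.55 for Klf4, 1.53 for Nqo1, 1.28 for Pfkfb3, 1.22 for Ddit3, 0.78 for Hspa5 and 0.56 for Myh6. With APC they were 1.93 for Fabp4, 1.55 for Gbp2, 1.42 for Cxcl10, 1.34 for Rsad2, 1.24 for Gch1, 1.11 for Irgm2 and 0.59 for Myh6. Control probe sets, which no comparison of genes used, differed from CTL in the middle to 3′ beta-actin ratio (2.33 in IPC_TRI and 2.33 in APC_TRI) and in the GAPDH ratio (1.10 and 1.15).

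The many calls of the trigger groups might come from changes in transcripts, from single probe sets or from RNA quality. Second probe sets had the same sign in 68.6% of genes in IPC_TRI and 65.5% in APC_TRI, with 95% intervals (59.2 to 76.7 and 52.7 to 76.4) that span the 70% written before the test. The changes predicted from the beta-actin 3′ to 5′ ratio correlated with the measured ones at r = 0.11 and r = 0.13, between the limits of 0.1 and 0.3 written before the test, so neither explanation was decided. That ratio did not pass against CTL (exact permutation adjusted p = 0.060 in IPC_TRI and 0.11 in APC_TRI). The middle to 3′ beta-actin and the GAPDH ratios, which set all trigger arrays above CTL, were not tried as predictors. With the 3′ to 5′ ratio as a covariate 361 of 869 and 219 of 453 calls were kept. The median size fell from 0.87 to 0.79 and from 0.84 to 0.79, and the median SE rose from 0.23 to 0.27 and from 0.21 to 0.23. Without IPC_TRI 5, 519 of the 869 calls were kept in direction, which argues against 1 aberrant array as the source of the IPC_TRI calls. The labels and files gave no scan or hybridization dates, so whether the trigger arrays were processed apart from the others was not tested. This stays open for the trigger calls and for each comparison that uses these arrays.

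The lower cytokine, chemokine and adhesion list in ISCH could follow from lower transcript levels, a loss of endothelial and myeloid cells, or scaling. The median change of 17 endothelial and myeloid markers outside the list was 0.14, above -0.47, the limit for cell loss. Its bootstrap 95% interval (-0.02 to 0.64) resampled the genes and not the arrays, so it leaves out the spread between hearts. As a set these 17 markers were not lower in ISCH. The limit was written after the values were seen, and the set leaves out endothelial markers of the cytokine list that fell, Sele and Selp. The markers therefore cannot decide about cell loss. The list median was -0.94 with the values as deposited and -0.95 with median centring, which argues against scaling. What set the high level of these genes in CTL stays open.

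The fibroblast list, higher in ISCH than in CTL, IPC and APC, might reflect transcript levels, 1 array, a lower share of cardiomyocytes or the amount of labelled target. Without ISCH 1 the medians were 0.62 against CTL, -0.51 for IPC and -0.64 for APC, which argues against that array. A lower share of cardiomyocytes would raise markers of all other cells. Myeloid markers had 0.0520 (9 genes, upper bound 0.14 against a limit of 0.32), endothelial markers 0.53 (8 genes, 0.19 to 0.74) and smooth muscle markers 0.05 (7 genes, -0.08 to 0.63). By the rule written before the test this argues against a lower share. These bounds too came from resampling genes and leave out the spread between hearts. With the spike signal as a covariate the median was 0.64, which by the rule written before the test counted against the amount of target. That value rests on 1 within-group slope (-0.00898) without an error, and the spike signal was itself higher in ISCH than in CTL. The amount of target therefore stays undecided. A rise of fibroblast and endothelial cells alone stays open.

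The arrays of each comparison were also divided in up to 100 ways, the real one included, and calls were counted in each. The real count was the highest for ISCH minus CTL (1 of 100 splits as large; 460 against at most 49), IPC_TRI minus CTL (1; 869 against 248), APC_TRI minus CTL (1; 453 against 15), APC minus ISCH (1; 14 against 8), IPC minus CTL (1; 204 against 24), APC minus CTL (1; 192 against 19), IPC minus IPC_TRI (1; 1228 against 579) and APC minus APC_TRI (1; 928 against 103). It was the highest too for the interactions with IPC (1; 714 against 74) and APC (1; 431 against 8), the average contrast (1; 1498 against 268) and the F test (1; 1658 against 9). It was the highest for the mean of IPC and APC against ISCH as well (1; 44 against 18). IPC minus ISCH had 4 of 100 splits as large, with 9 calls and at most 99 in another split, and IPC_TRI minus APC_TRI 2 of 100, with 23 and at most 43. Each share was under the 5% written before the test, and the shares were not adjusted over the 16 comparisons divided in this way. For the interactions and the contrasts of averages the labels were shuffled over all groups of the contrast. Group differences then entered the spread of the other splits, so these shares cannot decide about the contrast itself. With only their own groups in the fit IPC minus ISCH and IPC_TRI minus APC_TRI had 0 calls. IPC minus ISCH also had 0 without IPC 2 or without IPC 4. Chance is therefore not excluded for either comparison. The split with 99 calls, several times the real count, points to a structure among the IPC and ISCH arrays, whose source was not tested. IPC minus APC had 0 calls in the real split and at most 0 in the others, with 100 of 100 as large.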

How the results depend on the processing

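The alternatives moved counts more often than directions. A pseudocount of 1 left 196 named-gene values the same and ended 2 calls, a pseudocount of 64 left 199 the same and ended 1, and both left the 52 shifted lists the same. Over single arrays left out in turn 2156 gene values were the same, 161 lost their call and 3 gained one, and for lists 662 were the same and 28 lost theirs. Counts ran from 313 to 452 in ISCH minus CTL, 567 to 1076 in IPC_TRI minus CTL, 282 to 474 in APC_TRI minus CTL, 0 to 89 in IPC minus ISCH, 1 to 33 in APC minus ISCH, 156 to 190 in IPC minus CTL and 172 to 181 in APC minus CTL. They ran from 941 to 1363 in IPC minus IPC_TRI, 706 to 895 in APC minus APC_TRI, 0 to 1 in IPC minus APC, 8 to 91 in IPC_TRI minus APC_TRI, 506 to 882 and 301 to 425 in the interactions, 1333 to 1704 in the average contrast and 1470 to 1822 in the F test. Except where stated, the cause was not tested.

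With the values as deposited, IPC minus ISCH had 22 calls, APC minus ISCH 54 and IPC minus APC 1; with median centring they had 16, 39 and 1. Myh6 turned to 0.0822 in ISCH minus CTL and 0.0942 in IPC_TRI minus CTL with the values as deposited, and to 0.0782 and 0.0468 with median centring. The sarcomere list, whose middle member is Myh6 in ISCH minus CTL under both, turned to 0.0822 and 0.0782 there, and its test turned in APC minus ISCH (medians 0.0138 and 0.0727). The endoplasmic reticulum stress list lost its call in ISCH minus CTL (0.35 and 0.34), and ribosomal proteins in APC minus ISCH with median centring (-0.05). Without a filter IPC minus ISCH had 2 calls and APC minus ISCH 8; with 60% left out APC minus ISCH had 35, IPC minus APC 1 and IPC_TRI minus APC_TRI 15. With only the groups of the contrast in the fit, and so fewer arrays for the variance, counts were 238 in IPC_TRI minus CTL, 821 in APC_TRI minus CTL, 0 in IPC minus ISCH, 6 in APC minus ISCH, 298 in APC minus CTL, 526 in IPC minus IPC_TRI, 0 in IPC_TRI minus APC_TRI, and 452 and 786 in the interactions.

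A block for the replicate number gave 2 calls in IPC minus ISCH, ended the sarcomere list's call in APC minus ISCH (0.16) and those of Pnmt, Col5a1 and Notch1 in IPC minus ISCH and Hspb6 in IPC_TRI minus CTL, and changed no other named call. Arrays with the same number correlated at a mean of 0.0116 after group means were removed (-0.151 to 0.207; 9 of 75 pairs over 0.1), other pairs at -0.00198, and 10 of 30 arrays correlated best with their own number, so the arrays were not treated as paired.

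With the mean over each gene's probe sets, immediate early genes in IPC minus ISCH (0.18) and the sarcomere list in APC minus ISCH (0.16) lost their calls. With an estimated correlation 8 list calls held and 44 were lost at unchanged medians, since the test allows for genes that move together. In ISCH minus CTL these were immediate early genes 0.29, heat shock 0.20, endoplasmic reticulum stress 0.32, fatty acid oxidation -0.31, glycolysis -0.22, citric acid cycle -0.37, sarcomere -0.19, ribosomal 0.29, fibroblast 0.64 and adipocyte 0.29. In IPC minus ISCH they were immediate early genes 0.21, cytokines 0.23, glycolysis 0.19, citric acid cycle 0.27, ribosomal -0.17 and fibroblast -0.58; in APC minus ISCH glycolysis 0.19, citric acid cycle 0.30, sarcomere 0.16, ribosomal -0.15, smooth muscle -0.31 and fibroblast -0.70. They were heat shock 0.29 and endoplasmic reticulum stress 0.17 in IPC minus CTL, and heat shock 0.27 in APC minus CTL. For immediate early genes, heat shock, endoplasmic reticulum stress and cytokines they were 0.70, 0.63, 0.56 and -0.52 in IPC minus IPC_TRI and 0.50, 0.53, 0.51 and -0.67 in APC minus APC_TRI. They were cytokines 0.15 in IPC minus APC; cytokines 0.67, fatty acid oxidation 0.46, citric acid cycle 0.54 and fibroblast -0.48 in the interaction with IPC; fatty acid oxidation 0.46, citric acid cycle 0.35 and fibroblast -0.55 in that with APC; and heat shock 0.33, endoplasmic reticulum stress 0.45 and fibroblast 0.51 in the average contrast.

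Lists that lost their call without 1 array had medians of 0.24 to 0.37 (adipocyte), 0.14 to 0.47 (endoplasmic reticulum stress) and -0.23 to -0.16 (sarcomere) in ISCH minus CTL, 0.17 to 0.41 (cytokines) in IPC minus ISCH, 0.14 to 0.23 (sarcomere) and -0.40 to -0.26 (smooth muscle) in APC minus ISCH, and 0.0917 to 0.29 (cytokines) in IPC minus APC. In the interactions they had 0.51 to 0.84 (cytokines, IPC), -0.68 to -0.35 (fibroblast, IPC) and 0.38 to 0.57 (fatty acid oxidation, APC), and in the average contrast 0.43 to 0.55 (fibroblast).

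Alternatives chosen after seeing the data moved more counts. Without IPC_TRI 5 and ISCH 1 together APC_TRI minus CTL had 816 calls, APC minus ISCH 39 and IPC_TRI minus APC_TRI 91, and the cytokine list lost its call in IPC minus ISCH (0.17) and in the interaction with IPC (0.47). The 8 named genes that lost their call there were Acadsb, Cryab, Hspb6 and Hmox1 in IPC_TRI minus CTL, Pnmt and Notch1 in IPC minus ISCH, and Gpam and B4galt1 in the interaction with IPC. With array weights the counts were 933 in ISCH minus CTL, 394 in IPC_TRI minus CTL, 1065 in APC_TRI minus CTL, 267 in IPC minus ISCH, 203 in APC minus ISCH, 398 in IPC minus CTL, 383 in APC minus CTL, 794 in IPC minus IPC_TRI, 1518 in APC minus APC_TRI, 1 in IPC minus APC, 13 in IPC_TRI minus APC_TRI and 990 in the interaction with APC. Named calls were lost for 18, each given above. Calls were gained for 2, Nppb in ISCH minus CTL (-0.47) and Pnmt in IPC minus APC (-1.62). With the beta-actin ratio as a covariate they were 430 in IPC_TRI minus CTL, 274 in APC_TRI minus CTL, 3 in APC minus ISCH, 255 in IPC minus IPC_TRI, 614 in APC minus APC_TRI, 41 in IPC_TRI minus APC_TRI, 440 in the interaction with IPC, 487 in the average contrast and 749 in the F test; 34 named calls were lost. With the spike signal as a covariate they were 157 in ISCH minus CTL, 0 in IPC minus ISCH, 0 in APC minus ISCH, and 70 and 36 in the interactions; 36 named calls were lost and 1 was gained, Hmox1 in APC_TRI minus CTL (0.59).

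The mean of IPC and APC against ISCH, itself chosen after seeing the data, called 44 probe sets. It called 97 with the values as deposited, 96 with median centring, 21 without a filter, 67 with 60% left out, 37 with only its 3 groups in the fit, 399 with array weights, 41 with the beta-actin ratio and 0 with the spike signal as a covariate. Leaving out 1 array at a time gave 7 (ISCH 3) to 159 (IPC 5).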

Other observations

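The lists of interferon-induced and cholesterol synthesis genes and the added contrast were chosen only after results were seen. List p-values in this section are adjusted over these lists alone, not over the fixed lists. Of 19 interferon-induced genes 18 fell in ISCH minus CTL and 0 rose, with a median of -2.32. The list was written after Mx2, Cxcl10, Rsad2 and Gbp2 had been seen among the largest falls and holds them, so no list p is given for comparisons with CTL. Besides Mx2, Cxcl10 and Rsad2, Irf7 (-2.33), Stat2 (-2.32), Oas1a (-1.61) and Ifitm3 (-1.43) fell, and B2m (-0.14) did not pass; Cxcl10 and Irf1 also stand in the cytokine list. In IPC minus CTL 18 fell (median -1.91) and in APC minus CTL 19 (median -2.21). Fewer members passed in the trigger groups: 12 fell in IPC_TRI minus CTL (median -1.06) and 4 in APC_TRI minus CTL (median -0.78). The mean signal of Rsad2 was 8062 ± 1210 in CTL, 3593 ± 2300 in IPC_TRI, 3707 ± 1076 in APC_TRI and 436 ± 64.6 in ISCH (SD, n = 5). The list did not pass in IPC minus ISCH (0.11, adjusted p = 0.18) or APC minus ISCH (-0.11, adjusted p = 0.16), and stood higher in IPC than in APC (0.28, adjusted p = 4.7e-06; adjusted p = 0.14 with an estimated correlation) with 0 members past. Between the triggers it stood lower in IPC_TRI (-0.29, unadjusted camera p = 0.014, adjusted p = 0.028; adjusted p = 0.43 with an estimated correlation).

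Taking IPC and APC together against ISCH, 10 arrays against 5, 44 probe sets passed, 15 higher and 29 lower, with 11 genes up and 10 down. The count was not stable, from 0 with the spike signal as a covariate, which was higher in ISCH than in CTL, to 399 with array weights. Over 26 such settings Notch1 and Col5a1 kept their calls in 25, Fstl1 and Sparcl1 in 21, Nrp1 in 17, Col3a1 and Alas1 in 11, Fdft1 in 10 and Casq2 in 9. No called gene changed sign in them, the spike signal included. Notch1 ran from -1.03 to -0.83, Col5a1 from -0.98 to -0.80, Fdft1 from 1.06 to 1.93 and Casq2 from 0.31 to 0.67. The 10 that fell were Col3a1 (-1.15 ± 0.28, adjusted p = 0.042), Fstl1 (-1.01 ± 0.22, adjusted p = 0.024), Notch1 (-0.92 ± 0.16, adjusted p = 0.0078), Col5a1 (-0.89 ± 0.17, adjusted p = 0.013), Rpl19l4 (-1.01), Nrp1 (-0.78), Sparcl1 (-0.75 ± 0.16), Gpx3 (-0.75), Npr1 (-0.60) and Cryaa (-0.58). Fdft1, which makes squalene in cholesterol synthesis, rose by 1.68 ± 0.40 (adjusted p = 0.038), as did Casq2 (0.54), which binds calcium in the sarcoplasmic reticulum, and Alas1 (0.73), the first enzyme of haem synthesis. In ISCH minus CTL, Fdft1 fell by 2.13 and Acat2 by 0.57, while the list of 9 cholesterol synthesis genes did not pass (adjusted p = 0.67).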
